A study of Rattus norvegicus with 18 samples.

How the data were processed

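Total RNA from the amygdala, hippocampus and cortex of rats was measured on 18 Affymetrix rat expression arrays, 3 for each of the 6 combinations of region and treatment, where the treatment was chronic immobilization stress or handling alone. Region and treatment were taken from the title and the description of each array. A further label field named the amygdala for all 18 arrays, so transcripts known to mark each region were checked against the titles. Most followed the titles where hippocampus was compared. Between amygdala and cortex the match was partial. There 5 of 14 neocortex markers passed as higher in cortex and 3 as lower, and 5 of 9 amygdala markers passed as higher in amygdala and 1 as lower. The labels do not say whether the 3 arrays of a group came from separate animals, from pools or from repeats of the same RNA. The p-values therefore measure only the spread between these arrays, which may be technical. Nor do the labels say whether the 3 regions were taken from the same animals. The averaged stress effect and the comparisons between regions treat all arrays as independent, which may not hold.

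The deposited values are intensities on a linear scale, 1 per probe set and array, for 31099 probe sets. The software and the method that summarised the probes of a probe set are not given in the sources used here. From the values themselves, the authors had scaled each array to a common mean, because the mean after trimming 2% from each tail was 150.04 or 150.05 on all 18 arrays. No further scaling was applied. This kind of scaling fixes the mean intensity of every array, so a change shared by most bright transcripts cannot be seen. Detection calls, probe-level values and scan dates were not used here, and no processing batch could be tested.

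Probe sets were named from the platform's annotation, with symbols brought up to date from a rat RefSeq gene table through the Entrez identifier or, failing that, the transcript accession. Of the 31099 probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none, and the named ones covered 14218 symbols. Probe sets with several symbols or none were tested but not named. The 57 control probe sets were left out of the tests. The annotation is not tied here to positions within transcripts, so it is not known which part of a transcript a probe set reads.

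Values were analysed as log2 of the intensity plus 16, an offset that damps differences between values near the floor and so makes the changes of dim transcripts smaller than the ratio of their intensities. Probe sets whose mean lay at or above the 40th percentile were kept, which left 18625 probe sets with 10256 named genes. Group means were fitted over all 18 arrays with limma 3.58.1 in R 4.3.3, with 1 shared estimate of the spread per probe set (12 residual degrees of freedom, 10.2 prior degrees of freedom) and a trend of the variance with intensity. The contrasts were stress minus handled in each region, the mean of these 3, the differences between regions in the stress effect, and the differences between regions in the handled arrays. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18625 probe sets of a contrast and a threshold of 0.05 on the adjusted p. A difference of 3 against 3 arrays tested alone by exact permutation could not go below a p of 0.1, because there are only 10 splits, and so no single gene was tested that way. Errors beside log2 changes are standard errors from limma, and errors beside intensities are standard deviations over the 3 arrays of a group (n = 3 throughout).

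Shifts of 29 gene lists were tested with limma's camera and its preset correlation between genes of 0.01, with 1 probe set per gene, the one of highest mean. The 28 lists with at least 5 measured genes gave 84 pairs of list and region, over which p-values were adjusted together. The same test with an estimated correlation, and limma's fry, were run beside it. The same lists were tested for differences between regions, as a second family of 84. Sharing of the stress effect between regions was measured as the Pearson correlation of the log2 changes across probe sets, which are not independent replicates, and set against 100 splits that reassigned the stress and handled labels among the 6 arrays of each region, the real split included, in some of which all labels of a region were kept or turned.

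The lists, the tests and the rule for naming genes were fixed before the data were examined. For each regional stress contrast the text names up to 10 genes per direction with the largest change among those past the threshold whose 3 stress and 3 handled arrays did not overlap, 8 genes of the stress response (Nr3c1, Nr3c2, Fkbp5, Sgk1, Tsc22d3, Crh, Bdnf and Fos), and members of the lists. The averaged effect has up to 10 genes per direction, of 1 sign in all 3 regions, and the differences between regions up to 5 per direction. Genes named outside this rule are identified as such.

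The fit was tested on simulated arrays with the spread of the real ones, in which 100 probe sets were changed by 0.50 and another 100 by 1.00 on the log2 scale. In the amygdala 44% and 87% of these were called, in the hippocampus 46% and 81%, and in the cortex 30% and 92%. False calls numbered 7 of 138, 4 of 131 and 5 of 127. A simulated list shifted by -0.25 in the amygdala was called by camera, and 0 of 20 unshifted lists were. The simulated noise was drawn independently for each probe set, with the same spread on every array, and the lists were random probe sets. These rates therefore do not cover outlying arrays or correlated genes, such as the ribosomal list with an estimated correlation of 0.276.

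The alternatives were an offset of 1 or 64, quantile normalization, median centring, no filter or a filter at the 60th percentile, no variance trend, array quality weights, only the arrays of the groups compared, the number in the label as a fixed or random block, and leaving out each array in turn. A run without both arrays that agreed least with their groups (amygdala stress 1 and hippocampus handled 1) was added after the data had been seen, as were some of the alternatives for the gene lists and for the sharing between regions. Figures were drawn, and tables prepared, with Python 3.11.15.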

Results

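Gene expression was compared between rats exposed to chronic immobilization stress, whose schedule the labels do not give, and handled rats, in the amygdala, hippocampus and cortex. Each of the 6 groups had 3 arrays. Median intensities of the 18 arrays lay between 49.1 and 56.4, against a highest value of 20582 on any array. Arrays separated by region along the first principal component, which held 39.6% of the variance and set the hippocampus apart, and along the second, with 17.1%, which parted amygdala from cortex. On the third, with 6.39%, the 3 stress arrays scored higher than the 3 handled arrays in every region. The mean Spearman correlation of an array with the others of its group was lowest for hippocampus handled 1, at 0.934, and amygdala stress 1, at 0.935, and highest for cortex stress 3, at 0.969.

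**Figure D1:**
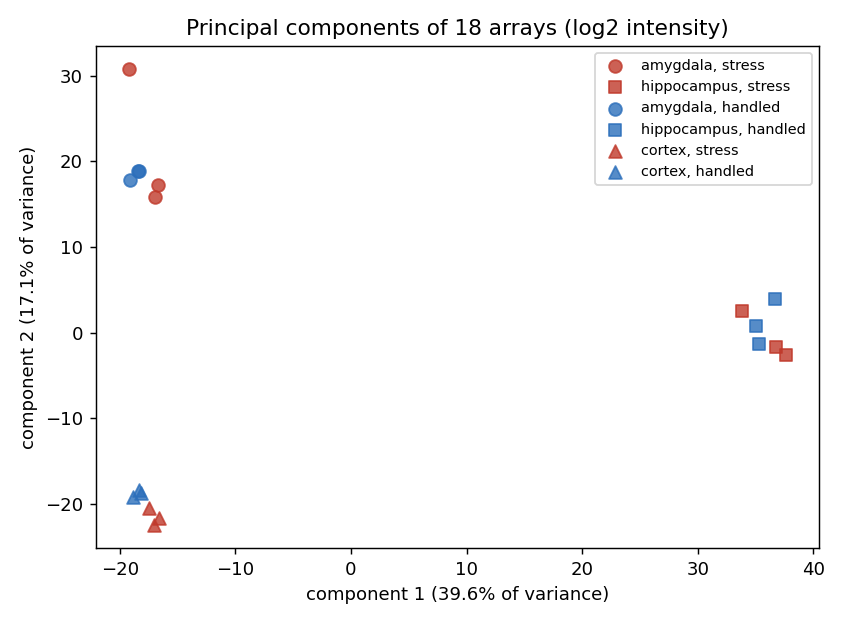
Scores of the 18 arrays on principal components 1 (39.6% of the variance, horizontal) and 2 (17.1%, vertical) of the log2 intensities, with 1 symbol per array, shape for the region and colour for the treatment. The arrays form 3 groups by region, and amygdala stress 1 lies highest on component 2.

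The handled arrays showed how the regions differed without stress. In the hippocampus Prox1, a transcription factor of dentate granule cells, had an intensity of 604 ± 14.4 against 75.7 ± 5.71 in cortex and 102 ± 6.82 in amygdala. The serotonin receptor Htr1a (134 ± 7.17) and the mineralocorticoid receptor Nr3c2 (1113 ± 95.5) were also brightest there. The amygdala had more Penk, which encodes the opioid precursor proenkephalin, than the cortex (1597 ± 106 against 389 ± 1.70, log2 difference 1.99 ± 0.09, adjusted p = 8.29e-13), along with the transcription factors Nr2f2 (2.66 ± 0.19) and Pbx3 (1.93 ± 0.10) and the receptor Trhr (1.94 ± 0.12). The cortex exceeded the hippocampus in Foxp2 (log2 difference, hippocampus minus cortex, -3.52 ± 0.21), Rprm (-3.44 ± 0.14), Nxph3 (-3.29 ± 0.16), Fxyd6 (-3.08 ± 0.16) and Rgs4 (-3.01 ± 0.10). It exceeded the amygdala in the adrenergic receptor Adra1d (-2.36 ± 0.13), in Bmper (-2.12 ± 0.28), and in the extracellular matrix genes Ogn (-2.21 ± 0.16), Col3a1 (-2.10 ± 0.16) and Col1a2 (-2.08 ± 0.16), which are expressed by meningeal fibroblasts. Between amygdala and hippocampus, Foxp2 (3.60 ± 0.21), Rprm (3.43 ± 0.14), Hpcal1 (3.26 ± 0.13), Camk2d (3.21 ± 0.08) and Penk (3.20 ± 0.09) were higher in amygdala, and Adra1d (-3.08 ± 0.13), Homer3 (-2.97 ± 0.17), Rem2 (-2.83 ± 0.19), Prox1 (-2.40 ± 0.09) and Hpca (-2.32 ± 0.07) were lower. Rem2 (2.94 ± 0.19), Rerg (2.85 ± 0.11) and Homer3 (2.77 ± 0.17) were also higher in hippocampus than in cortex.

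Ttr, which encodes the thyroid hormone carrier transthyretin and is made in the choroid plexus, had the largest excess in hippocampus over cortex, 1102 ± 55.0 against 54.5 ± 12.8 (4.002 ± 0.14), and in amygdala over cortex (2.92 ± 0.14). Of the 8 measured hippocampus markers 7 passed as higher in hippocampus than in cortex, and 7 as higher than in amygdala, the other being Nnat, which was lower. Amygdala markers passed as higher in amygdala for 8 of 9 genes against hippocampus and for 5 of 9 against cortex, with Pnoc lower in both. Neocortex markers passed as higher in cortex for 11 of 14 against hippocampus, with Neurod6 and Rasgrf2 opposite, but for only 5 of 14 against amygdala, with Ccn2, Etv1 and Tshz2 opposite. In all, limma called 2738 probe sets between amygdala and cortex (1516 higher in amygdala), 4815 between hippocampus and cortex (2278 higher in hippocampus) and 5289 between amygdala and hippocampus (2895 higher in amygdala). With median centring the majority turned for both amygdala contrasts, to 1093 higher and 1687 lower against cortex and 2405 higher and 2781 lower against hippocampus.

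In the amygdala, transcripts of several glutamate and GABA receptors were lower in the stress arrays. Gria1, an AMPA receptor subunit, had an intensity of 513 ± 75.5 after stress and 1065 ± 217 after handling (log2 change -1.02 ± 0.12, adjusted p = 5.84e-05). The NMDA receptor subunits Grin2b (-0.86 ± 0.17), Grin3a (-0.80 ± 0.17) and Grin2a (-0.67 ± 0.10) and the metabotropic receptor Grm5 (-0.81 ± 0.17) fell as well. These were the 5 of 25 measured glutamate receptors and transporters that passed over all probe sets, and the remaining 20 did not. Adjusted over the list alone, 5 were lower and 1 was higher. One of the 3 probe sets of Grin2a had the opposite sign. The list as a whole lay lower, with a median of -0.07 (camera adjusted p = 0.0126), and this was lost with an estimated correlation (adjusted p = 0.0649). Of 15 measured GABA signalling genes, Gabra2 (-0.64 ± 0.13) and Gabbr2 (-0.33 ± 0.07), which encode receptor subunits, and the GABA-synthesising enzyme Gad2 (-0.67 ± 0.18) fell, and the same number, 3, passed adjusted over the list alone. The list median was -0.04 (adjusted p = 0.0132, and 0.0773 with an estimated correlation). Without amygdala stress 1 neither list was called (adjusted p = 0.0548 for GABA signalling, 0.0529 for glutamate), and the GABA list was also not called without amygdala handled 1 (adjusted p = 0.0602). The glutamate list was not called with the filter at the 60th percentile (adjusted p = 0.0742). The stress amygdala arrays that gave these lower values also had a larger 3′ to 5′ difference of the hexokinase control, an index of RNA integrity (1.23 ± 0.07 log2 against 0.83 ± 0.08), with beta-actin (2.15 ± 0.24 against 2.07 ± 0.08) and GAPDH (0.45 ± 0.08 against 0.45 ± 0.04) alike, and the added dap control transcripts were dimmer on them by 0.57 log2. Hexokinase was also higher after stress in hippocampus (1.17 ± 0.15 against 1.02 ± 0.11) and cortex (1.28 ± 0.12 against 1.11 ± 0.09).

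Other transcripts fell further. Pnma8b had intensities of 318 ± 10.4 and 862 ± 181 (log2 change -1.38 ± 0.15, adjusted p = 1.50e-05). Ahi1, which acts at the primary cilium and is mutated in Joubert syndrome, fell by 1.18 ± 0.12 with both of its probe sets called (adjusted p = 6.93e-06). The chromatin genes Dnmt3a, a DNA methyltransferase (-1.27 ± 0.17), Setd5 (-1.19 ± 0.14) and Atrx (-1.15 ± 0.21) fell, with 3 of 5 probe sets called for Atrx and all 5 of 1 sign. Further falls were those of Wdr33 (-1.27 ± 0.31), Vof16 (-1.23 ± 0.22), the calcium sensor Hpcal4 (-1.18 ± 0.13), Stox2 (-1.17 ± 0.18) and Dnajb14 (-1.16 ± 0.14). Wdr33, Vof16, Stox2, Dnmt3a and Atrx were dim on the stress amygdala arrays, with intensities between 12.6 and 45.3, so the size of their falls depends on the offset. One of 2 probe sets of Wdr33, 1 of 3 of Setd5 and 1 of 3 of Hpcal4 had the opposite sign. Over all genes called lower in amygdala, their other probe sets had a median change of -0.0577, against -0.597 for the called ones. For 65.1% of these genes the others were lower too, so a called fall need not hold for the whole gene. Of 38 dendrite, synapse and plasticity genes Cplx2 (-0.72 ± 0.12), Marcks (-0.30 ± 0.07) and Ncam1 (-0.40 ± 0.11) fell, and adjusted over the list alone 3 were lower and 2 higher. Camera did not call that list (adjusted p = 0.217), nor did fry (0.540). Reln (-0.47 ± 0.07), Xiap (-0.66 ± 0.11), Ccnd2 (-0.60 ± 0.12), Etv1 (-0.32 ± 0.08) and the cytokine receptor subunit Il6st (-0.36 ± 0.09) fell too.

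Among transcripts that rose, Gh1, growth hormone, went from 91.9 ± 15.9 to 209 ± 18.2 (log2 change 1.07 ± 0.17, adjusted p = 8.04e-04), and Scn4b, an auxiliary subunit of sodium channels, from 77.2 ± 11.3 to 165 ± 14.4 (0.96 ± 0.12, adjusted p = 7.47e-05). Mapk1ip1l (1.30 ± 0.23), Dhx34 (1.26 ± 0.32), the interferon-induced Rtp4 (1.10 ± 0.20), Syt15 (1.08 ± 0.25), Gas8 (0.85 ± 0.19), Homer3 (0.79 ± 0.17) and the major histocompatibility gene RT1-T24-3 (0.72 ± 0.16) rose as well, though the second probe set of Homer3 had the opposite sign. Dhx34, Rtp4, Syt15 and Mapk1ip1l were dim in the handled arrays, with mean intensities between 14.7 and 22.01. Of 22 neuropeptides and peptide receptors, Npy (0.39 ± 0.08), Penk (0.40 ± 0.09) and Pnoc (0.76 ± 0.19), which encode neuropeptide Y and opioid-family precursors, rose, the same 3 adjusted over the list alone. Camera did not call the list (adjusted p = 0.118), whereas fry did (adjusted p = 0.0117). Striatal neuron markers lay higher, with 11 of 12 above 0, a median of 0.29 (adjusted p = 0.00111) and an adjusted p of 0.0508 with an estimated correlation. Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, rose by 0.61 ± 0.11 and was the only member to pass, against 3 adjusted over the list alone. The amygdala adjoins the striatum, and whether the stress pieces held more of it was not tested. Wipf3 rose by 0.30 ± 0.07. Of 15 circadian clock genes Nr1d2 (0.28 ± 0.06), Bhlhe41 (0.28 ± 0.07), Dbp (0.36 ± 0.09) and Npas2 (0.34 ± 0.09) rose and Hlf fell (-0.42 ± 0.09, with its 2 other probe sets of opposite sign), the same 5 adjusted over the list alone, and neither camera (adjusted p = 0.480) nor fry (0.281) called that list. Both tests look for a shift in 1 direction and can miss genes that move in opposite ways. Fry's test for changes in either direction gave an unadjusted p of 8.1e-13 for the clock genes. Most lists were low by that test in amygdala, with 9.4e-10 for glutamate receptors and transporters, 1.1e-07 for interneuron markers and 0.018 for glucocorticoid-regulated genes. A low value was therefore not particular to the clock genes.

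**Figure D2:**
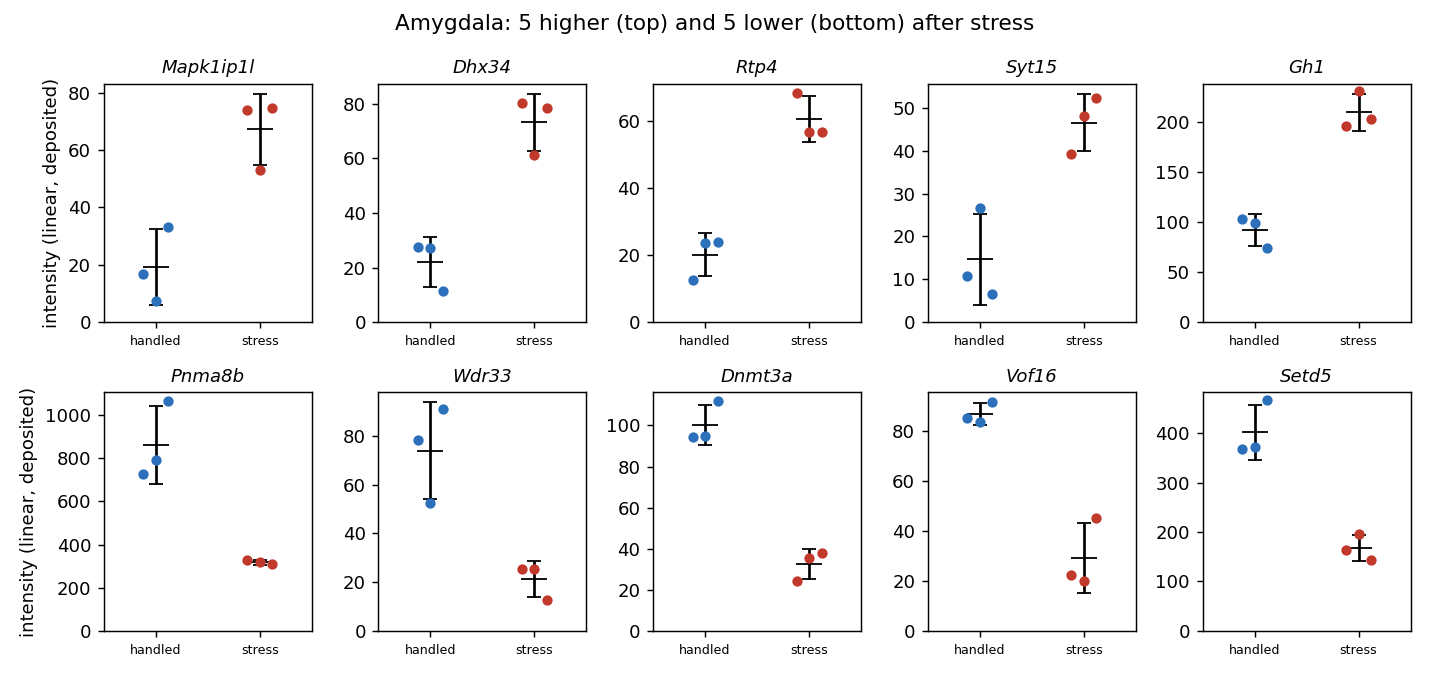
Linear intensity per array (vertical) of the 5 genes with the largest rise (top) and the largest fall (bottom) in the amygdala, with handled arrays in blue and stress arrays in red. Bars are the mean ± SD of 3 arrays. The 3 stress arrays lie apart from the 3 handled arrays in each gene because the genes were chosen that way.

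In total 447 probe sets of 310 genes passed in the amygdala, 85 higher and 362 lower (81.0%), with 35 changed at least 2-fold. The count was 197 without amygdala handled 3, 284 without amygdala stress 2 and 186 when only the amygdala arrays were fitted, of which 183 were among the 447. Of the 46 named genes that passed, 20 passed in every alternative, among them Gria1, Grin2a, Grin2b, Pnma8b, Ahi1, Dnmt3a, Gh1, Scn4b and Ppp1r1b. The other 26 each lost the call in at least 1, among them Dhx34, Syt15, Pnoc, Npy, Penk, Grm5, Grin3a, Gabra2, Gabbr2, Gad2 and the clock genes.

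In the hippocampus the largest change was that of Ttr, which rose from 1102 ± 55.0 to 3410.5 ± 137 (log2 change 1.62 ± 0.14, adjusted p = 4.65e-07). Sostdc1, another gene of the choroid plexus list, rose from 35.5 ± 5.05 to 81.4 ± 5.24 (0.92 ± 0.19, adjusted p = 0.0307). These were the 2 of 7 measured choroid plexus and ependyma markers that passed, against 3 adjusted over the list alone. The list median was 0.20 (adjusted p = 0.00406, and 0.0923 with an estimated correlation). Ace (0.89 ± 0.25), Folr1 (0.20 ± 0.21), Calml4 (0.07 ± 0.23), Foxj1 (-0.23 ± 0.26) and Aqp1 (-0.58 ± 0.32) did not pass. In amygdala Ttr was also brighter on the 3 stress arrays (678, 701 and 721) than on the handled ones (558, 495 and 482). No gene of the choroid plexus list passed there over all probe sets, and 1 was higher adjusted over the list alone. Oligodendrocyte markers lay lower: 19 of 20 were below 0, with a median of -0.22 (adjusted p = 7.43e-13, and 0.00172 with an estimated correlation). Bcas1 (-0.30 ± 0.06) and the myelin tight junction protein Cldn11 (-0.30 ± 0.07) passed, 14 genes passed adjusted over the list alone, and the other 18 did not pass over all probe sets.

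Gh1 fell in the hippocampus, from 122 ± 17.7 to 48.8 ± 7.22 (-1.09 ± 0.17, adjusted p = 0.00211). The transcription factor Pou3f1 (-0.97 ± 0.14), Ldb2 (-0.82 ± 0.12) and Wfs1 (-0.71 ± 0.10), a marker of pyramidal cells of field CA1, fell, as did Topbp1 (-1.14 ± 0.20), Rtbdn (-0.92 ± 0.20), Gpr161 (-0.83 ± 0.16), Dnmt3a (-0.78 ± 0.17) and Pnma8b (-0.73 ± 0.15). The serotonin receptor Htr2c (0.56 ± 0.09), Pip5k1a (0.73 ± 0.13), Rprd1b (0.70 ± 0.12), Cdc73 (0.56 ± 0.10), Ildr2 (0.56 ± 0.08), Lrrc8b (0.52 ± 0.11) and Itih3 (0.39 ± 0.07) rose. The second probe sets of Topbp1, Pnma8b and Htr2c had the opposite sign. Topbp1 and Rtbdn were dim on the stress hippocampus arrays, with intensities between 11.4 and 28.9. Of the clock genes Dbp (0.47 ± 0.09) and Nr1d2 (0.33 ± 0.06) rose, the same 2 adjusted over the list alone, and neither camera (adjusted p = 0.218) nor fry (adjusted p = 0.270) called the list as shifted in 1 direction. Fry's test for changes in either direction gave an unadjusted p of 1.6e-11, but it was also low for other lists, at 6.4e-12 for oligodendrocyte markers.

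In all, 67 probe sets of 45 genes passed in the hippocampus, 19 higher and 48 lower. With median centring 50 passed, 25 in each direction. The count was 27 without hippocampus stress 2, 39 without hippocampus handled 2, 43 without hippocampus handled 1, 32 without the variance trend and 20 when only the hippocampus arrays were fitted. Of 23 named genes that passed, Ttr, Gh1, Pou3f1, Wfs1 and Hbb did so in every alternative, and the other 18 lost the call in at least 1.

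In the cortex the transcripts that fell most were those of fibroblasts and the meninges. Igf2, insulin-like growth factor 2, fell from 433 ± 28.4 to 142 ± 32.3 (log2 change -1.53 ± 0.12, adjusted p = 2.06e-07), the collagen gene Col1a2 from 199 ± 9.5024 to 63.4 ± 3.08 (-1.44 ± 0.16, both probe sets called), and Ptgds, prostaglandin D synthase, abundant in the leptomeninges, from 3056 ± 108 to 1395 ± 45.9 (-1.12 ± 0.06, adjusted p = 3.68e-11). Igfbp2 (-1.28 ± 0.12), Col3a1 (-1.22 ± 0.16), Ogn (-0.95 ± 0.16) and Lum (-0.87 ± 0.18) also fell. All 11 measured meningeal fibroblast markers lay below 0, 6 passed over all probe sets and 11 adjusted over the list alone. The list median was -0.91 (adjusted p = 1.45e-25, and 7.00e-06 with an estimated correlation). Cd74, the invariant chain of antigen presentation (-1.23 ± 0.17), the gap junction gene Gjb2 (-1.11 ± 0.15), Anp32a (-1.09 ± 0.22), Myl9 (-0.90 ± 0.20), the retinoic acid hydroxylase Cyp26b1 (-0.81 ± 0.08), Vim (-0.61 ± 0.10), Ccnd2 (-0.62 ± 0.12) and Gabbr2 (-0.42 ± 0.07) fell in the same arrays. All 11 list members were brighter in handled cortex than the mean of the other handled regions, and in stress cortex lay closer to it.

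**Figure D3:**
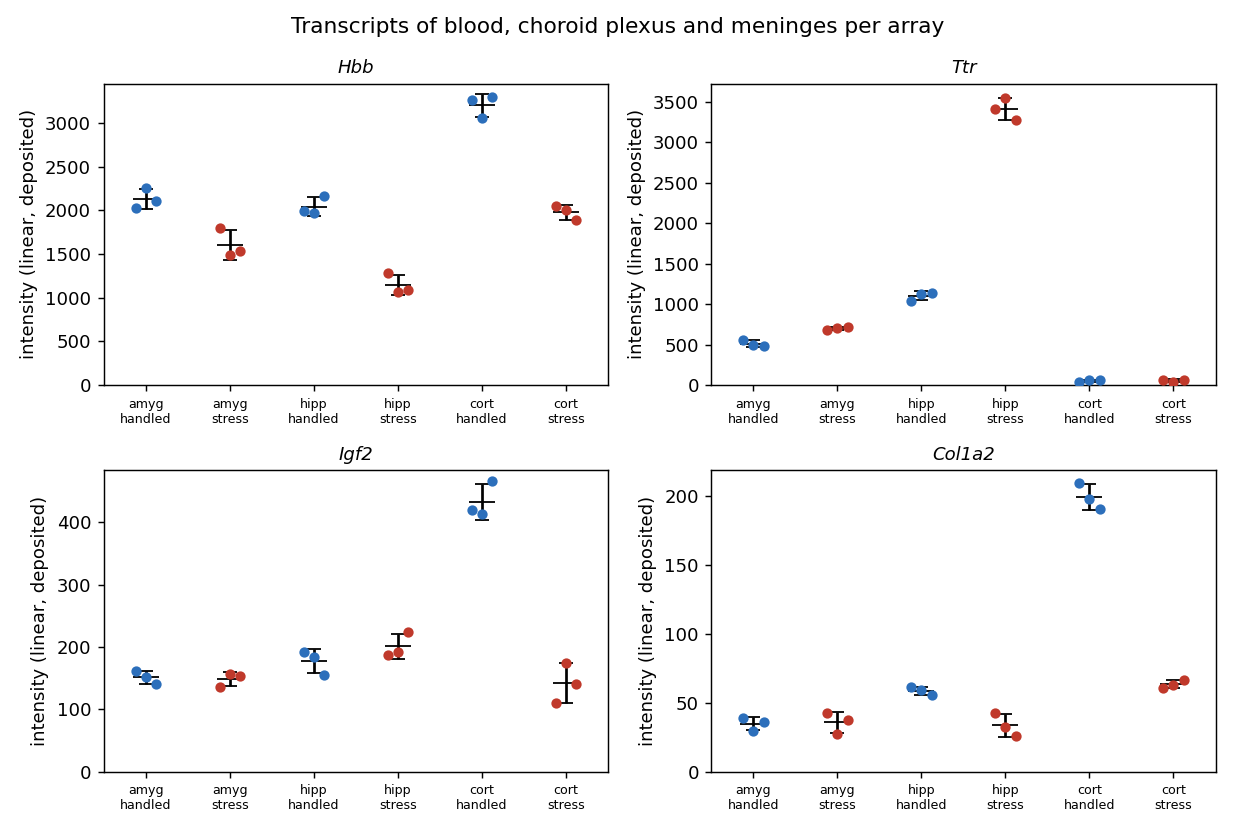
Linear intensity per array (vertical) of Hbb, Ttr, Igf2 and Col1a2 in the 6 groups, handled in blue and stress in red, with bars for the mean ± SD of 3 arrays. Hbb is lower after stress in each region, Ttr is higher in stress hippocampus and, by less, in stress amygdala, and Igf2 and Col1a2 are lower in stress cortex.

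Immediate early genes, which neuronal activity induces, lay lower in the cortex after stress. Of 22 measured, 18 were below 0, with a median of -0.19 (adjusted p = 5.52e-05, and 0.0163 with an estimated correlation). Fos went from 147 ± 10.9 to 71.8 ± 8.80 (-0.90 ± 0.18, adjusted p = 0.0197) and alone passed over all probe sets, while 5 passed adjusted over the list alone. Fos did not pass in amygdala (-0.57 ± 0.18, adjusted p = 0.106) or hippocampus (-0.04 ± 0.18, adjusted p = 0.961), and its stress effect did not differ between regions by test (adjusted p = 0.732 for amygdala against cortex, 0.513 for hippocampus against cortex). The call of Fos in cortex was lost in 5 of the 6 runs that left out 1 cortex array, and with no filter.

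Among the genes that rose in cortex, Htr2c went from 601 ± 7.04 to 893 ± 35.0 (0.56 ± 0.09, adjusted p = 0.00425). The neuropeptide neurotensin, Nts (0.89 ± 0.19), the nuclear receptor Nr1i2 (1.03 ± 0.23), Cdc73 (0.66 ± 0.10), Arhgap6 (0.64 ± 0.14), Ildr2 (0.58 ± 0.08), Spry2 (0.55 ± 0.09), Srp72 (0.53 ± 0.12), Lrrc8b (0.51 ± 0.11) and Tardbp (0.50 ± 0.10) rose as well, with 1 of 3 probe sets of Tardbp of opposite sign. Nr1i2 was dim in the handled arrays, at 10.2 ± 6.62. Endothelial and pericyte markers lay slightly lower (median -0.12, adjusted p = 0.0393, and 0.167 with an estimated correlation) and hippocampus markers slightly higher (median 0.21, adjusted p = 0.0426, and 0.167 with an estimated correlation). No member of either passed over all probe sets by limma, whereas 4 of 15 and 2 of 8 had an unadjusted p under 0.05 and 2 of each passed adjusted over the list alone. Both list calls were lost in several alternatives. No circadian clock gene passed over all probe sets in cortex, but 4 of 15 were higher and 1 lower adjusted over the list alone. Fry's test for changes in either direction gave an unadjusted p of 5.1e-12 for that list. It was also low for other lists, at 5.7e-14 for meningeal and 4.4e-10 for microglia markers.

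The cortex count was 75 probe sets of 55 genes, 25 higher and 50 lower. Leaving out any 1 cortex array gave 34 to 44: 37, 44 and 34 without stress 1, 2 and 3, and 36, 36 and 35 without handled 1, 2 and 3. It was 43 without the variance trend, 48 with no filter, 196 without the amygdala and hippocampus arrays that agreed least with their groups, 621 with array weights (293 higher, 328 lower) and 560 when only the cortex arrays were fitted (269 higher, 291 lower). Each of the last 3 runs called all 75. Of 27 named genes that passed, 14 did so in every alternative, among them Igf2, Col1a2, Ptgds, Cd74, Gjb2, Cyp26b1, Hbb, Htr2c, Cdc73, Ildr2 and Spry2.

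**Figure D4:**
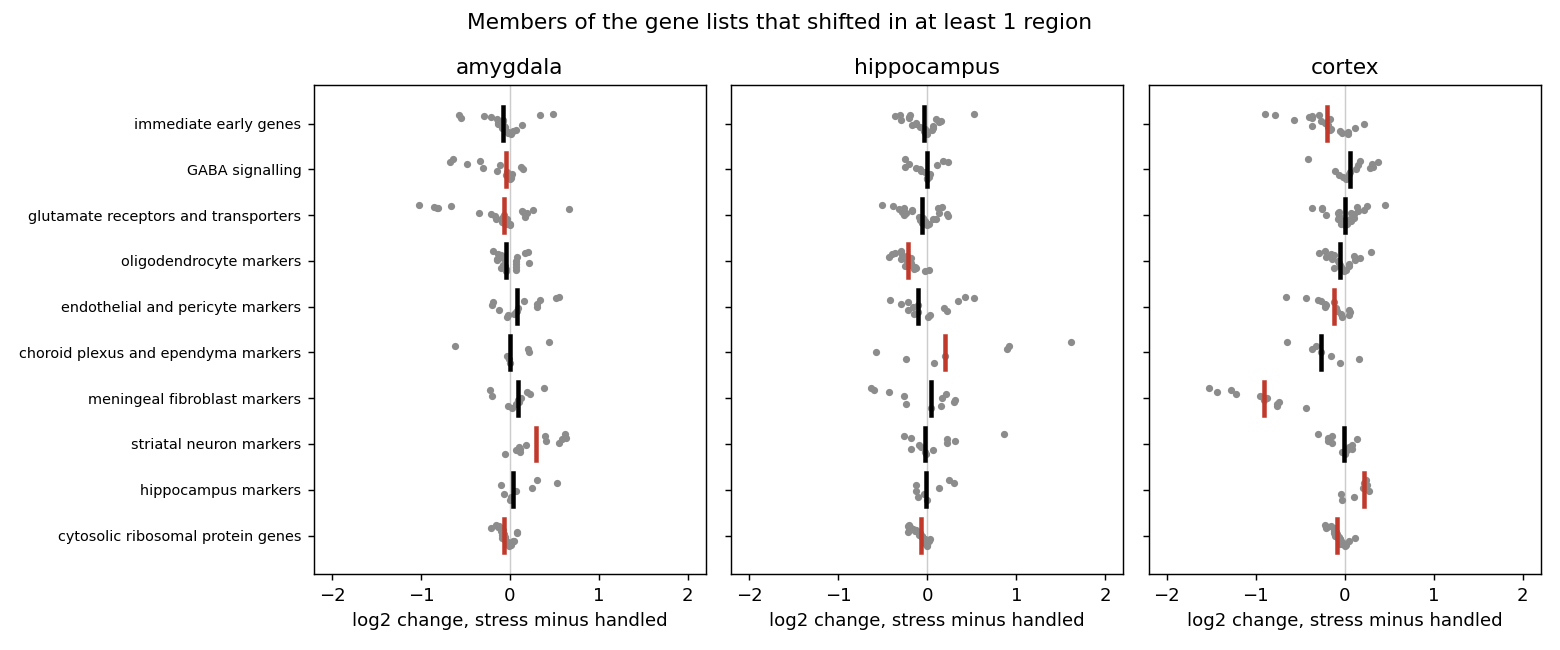
Log2 change, stress minus handled (horizontal), of the members of 10 gene lists in the 3 regions, with 1 grey point per gene and a bar at the list's median, red where camera called a shift at its preset correlation. The meningeal markers in cortex lie farthest from 0.

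The genes of the glucocorticoid response did not pass in any region. None of 27 measured glucocorticoid-regulated genes passed by limma, over all probe sets or adjusted over the list alone, and 2, 0 and 3 had an unadjusted p under 0.05 in amygdala, hippocampus and cortex. The list was not called by camera (adjusted p = 0.909, 0.889 and 0.919) or fry (0.781, 0.738 and 0.953), and in amygdala its median (0.02) and mean (-0.04) differed in sign. The glucocorticoid receptor Nr3c1 changed by 0.14 ± 0.09, -0.02 ± 0.09 and 0.07 ± 0.09 in the 3 regions. Its chaperone partner Fkbp5 changed by 0.18 ± 0.12, -0.14 ± 0.12 and 0.02 ± 0.12, Sgk1 by 0.12 ± 0.07, 0.13 ± 0.07 and 0.01 ± 0.07, and Tsc22d3 by 0.12 ± 0.08, 0.00 ± 0.08 and 0.16 ± 0.08. The mineralocorticoid receptor Nr3c2 (0.01 ± 0.08, -0.04 ± 0.08 and 0.22 ± 0.08), Crh (-0.17 ± 0.19, 0.12 ± 0.19 and -0.01 ± 0.19) and Bdnf (-0.14 ± 0.11, 0.16 ± 0.11 and 0.09 ± 0.11) also did not pass. The 2 probe sets of Fkbp5 in amygdala and hippocampus, and those of Bdnf in hippocampus and cortex, differed in sign. Cytosolic ribosomal protein genes lay slightly lower in all 3 regions, with medians of -0.07, -0.07 and -0.09 (adjusted p = 0.00132, 3.19e-06 and 1.33e-05), none of the 30 passed singly by limma over all probe sets, and 3, 9 and 9 had an unadjusted p under 0.05 (0, 6 and 1 passed adjusted over the list alone). These shifts were lost with an estimated correlation (adjusted p = 0.524, 0.428 and 0.428), with fry (adjusted p = 0.233, 0.0843 and 0.0843), and with quantile normalization in amygdala (adjusted p = 0.380) and cortex (0.264). The other 18 of the 28 tested lists, which include astrocyte, microglia, interneuron, heat shock, endoplasmic reticulum stress, mitochondrial, inflammation, hypoxia, cell death and neurogenesis genes, were called in no region by camera. Of these fry called 3, neuropeptides (adjusted p = 0.0117) and monoamine and acetylcholine signalling (adjusted p = 0.00143) as higher in amygdala and microglia markers (adjusted p = 0.0170) as lower in cortex.

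Averaged over the 3 regions, 868 probe sets passed, 297 higher and 571 lower. This average treats the arrays of the 3 regions as independent, and whether they came from the same animals is not known. Gucy1a2, a subunit of the nitric oxide receptor guanylate cyclase, fell by 1.04 ± 0.17 on average (-1.12, -1.13 and -0.87 in amygdala, hippocampus and cortex, adjusted p = 5.71e-04). Falls of Dnmt3a (-0.81 ± 0.10), Pnma8b (-0.75 ± 0.08), Topbp1 (-0.73 ± 0.11), Fbxo15 (-0.73 ± 0.10), Stox2 (-0.73 ± 0.11), Wdr33 (-0.70 ± 0.18) and Dnajb14 (-0.67 ± 0.08) went with those of the collagens Col1a2 (-0.84 ± 0.14) and Col1a1 (-0.78 ± 0.17). The averaged fall of Col1a2 came from a probe set that was also lower in amygdala (-0.66), where the brighter one was not (0.02). The second probe set of Topbp1 had the opposite sign. Rises were smaller, at 0.70 ± 0.15 for Eml2, 0.60 ± 0.11 for Rtp4, 0.60 ± 0.06 for Cdc73, a component of the PAF transcription complex, 0.58 ± 0.09 for RT1-T24-3, 0.54 ± 0.07 for Lrrc8b, 0.52 ± 0.07 for Pip5k1a, 0.45 ± 0.11 for Tpbg, 0.45 ± 0.05 for Htr2c, 0.44 ± 0.06 for Zcchc7 and 0.43 ± 0.12 for Uqcrc2. The averaged count was 570 without the variance trend.

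Only 14 probe sets passed in all 3 regions. Hbb, the beta chain of haemoglobin, fell in amygdala (-0.41 ± 0.07, from 2131 ± 116 to 1606 ± 169), hippocampus (-0.83 ± 0.07, from 2040.1 ± 107 to 1146 ± 115) and cortex (-0.69 ± 0.07, from 3205 ± 131 to 1979 ± 84.7). Only 2 genes of the red blood cell list were measured, too few for a list test. Lpar1, Inka2, Gda and Ensa fell and Cdc73 and Lrrc8b rose in every region, and the other 7 probe sets carried several symbols or none. Those with several symbols changed by -0.435 to -0.588 in amygdala, -0.83 to -1.111 in hippocampus and -0.613 to -1.018 in cortex, much like Hbb. Which genes they read was not resolved, so the 14 probe sets may not be 14 separate signals. The genes named in this paragraph were chosen after their values were seen.

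Over all probe sets tested, the stress effects of 2 regions correlated weakly. The correlation of log2 changes over the 18625 probe sets was 0.217 between amygdala and hippocampus, 0.116 between amygdala and cortex and 0.215 between hippocampus and cortex. Of 100 splits, the real one included, 1, 3 and 1 gave a correlation as high (one-sided permutation p = 0.01, 0.03 and 0.01, the first and last being the smallest that 100 splits can give, and 0.015, 0.03 and 0.015 after Benjamini-Hochberg adjustment over the 3). Lower calls were shared by 22 probe sets between amygdala and hippocampus, 21 between amygdala and cortex and 14 between hippocampus and cortex, against 0.933, 0.972 and 0.129 for independent lists. These counts include the lower probe sets that passed in all 3 regions, several of which may read the same transcript. Higher calls were shared by 5, 4 and 4, and opposite calls by 1, 1 and 0. Of the probe sets called in 1 region of a pair, between 78.7% and 86.6% had the same sign in the other. The share over all probe sets was not computed. The correlation of amygdala with cortex fell to 0.0347 without amygdala stress 2 and was 0.197 without amygdala stress 1, and that of amygdala with hippocampus was 0.126 without hippocampus stress 2. With the filter at the 60th percentile the 3 were 0.327, 0.209 and 0.329, and without both amygdala stress 1 and hippocampus handled 1 that of amygdala with cortex was 0.197.

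The stress effect differed between regions for few single genes. Gh1 rose in amygdala and fell in hippocampus, a difference of 2.16 ± 0.24 (adjusted p = 6.82e-05), and Wfs1 had the same direction of difference (0.99 ± 0.14, adjusted p = 0.00142). Among genes that fell in cortex, the change differed from amygdala for Igf2 (1.499 ± 0.18, adjusted p = 1.13e-04), Col1a2 (1.46 ± 0.22), Col3a1 (1.28 ± 0.23) and Ptgds (1.09 ± 0.08, adjusted p = 8.17e-08), and from hippocampus for Igf2 (1.69 ± 0.18), Igfbp2 (1.48 ± 0.18), Cd74 (1.39 ± 0.24) and Cyp26b1 (0.92 ± 0.11). The change in amygdala lay below that in cortex for Luzp2 (-1.24 ± 0.22), Pnma8b (-1.22 ± 0.21), Ahi1 (-1.15 ± 0.17), Gria1 (-1.13 ± 0.18) and Eif3c (-1.01 ± 0.20), and below that in hippocampus for Ahi1 (-0.97 ± 0.17), the cell adhesion gene Lsamp (-0.76 ± 0.13) and the synaptic vesicle gene Sv2b (-0.71 ± 0.12). The rise of Ttr in hippocampus differed from cortex (1.67 ± 0.20, adjusted p = 7.51e-05) and from amygdala (-1.17 ± 0.20, adjusted p = 0.0280). Gh1 also differed between amygdala and cortex (1.28 ± 0.24), Scn4b between amygdala and hippocampus (0.91 ± 0.17), and Nts (-1.70 ± 0.27), Pou3f1 (-1.04 ± 0.20), Ccn3 (-0.76 ± 0.11), Wfs1 (-0.71 ± 0.14) and Ywhab (-0.48 ± 0.09) between hippocampus and cortex. The second probe sets of Luzp2 and Ywhab had the opposite sign.

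Gene lists differed as well. The stress change in amygdala lay below that in cortex for GABA signalling (median difference -0.17, camera adjusted p = 0.00136) and glutamate receptors (-0.08, adjusted p = 0.00786) and above it for striatal markers (0.31, adjusted p = 9.66e-04) and, through the fall in cortex, meningeal markers (1.05, adjusted p = 8.18e-19). The change of oligodendrocyte markers lay lower in hippocampus than in amygdala (0.19, adjusted p = 3.40e-06) or cortex (-0.17, adjusted p = 1.01e-07), and that of neuropeptides lay higher in amygdala than in hippocampus (0.21, adjusted p = 0.00786). The stress change in hippocampus lay above that in cortex for choroid plexus markers (0.52, adjusted p = 4.20e-05) and, again through the fall in cortex, meningeal markers (0.91, adjusted p = 5.09e-18). These 9 held with an estimated correlation, and 8 other called differences did not. Lost were, between amygdala and hippocampus, striatal markers (estimated-correlation adjusted p = 0.0510), choroid plexus markers (0.0780), GABA signalling (0.0964) and dendrite and synapse genes (0.526), between amygdala and cortex, endothelial markers (0.0510), and between hippocampus and cortex, immediate early genes (0.0534), microglia markers (0.172) and dendrite and synapse genes (0.475).

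The interaction test called 9 probe sets between amygdala and hippocampus (5 higher, 4 lower), 24 between amygdala and cortex (9 higher, 15 lower) and 16 between hippocampus and cortex (8 higher, 8 lower). With median centring the splits were 3 higher and 12 lower for amygdala against hippocampus and 8 higher and 5 lower for hippocampus against cortex. The first count ranged from 3 to 18 when 1 array was left out, with 3 without amygdala handled 3, hippocampus stress 3 or hippocampus handled 2, 4 without hippocampus stress 1 or hippocampus handled 1, 5 without hippocampus handled 3 and 18 without hippocampus stress 2. The second was 45 without amygdala stress 3, 15 without amygdala handled 3, 14 without cortex stress 2 or 3 or cortex handled 1 or 2, and 11 without cortex handled 3, and the third was 10 without cortex stress 3 or handled 3. The first count was also 3 with no filter, without the variance trend or with array weights, 4 with only the groups compared, 16 with the filter at the 60th percentile and 14 without both amygdala stress 1 and hippocampus handled 1. The second was 15 with no filter, 9 without the trend and 60 with array weights.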

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

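The tests below of meningeal tissue, choroid plexus and control transcripts were chosen after the results they bear on had been seen.

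The stress effect differed between regions for 9 probe sets (amygdala against hippocampus), 24 (amygdala against cortex) and 16 (hippocampus against cortex). Amygdala minus hippocampus differed for Gh1 (2.16), Wfs1 (0.99), Scn4b (0.91), Ttr (-1.17), Ahi1 (-0.97), Lsamp (-0.76) and Sv2b (-0.71). Amygdala minus cortex differed for Igf2 (1.499), Col1a2 (1.46), Col3a1 (1.28), Gh1 (1.28), Ptgds (1.09), Luzp2 (-1.24), Pnma8b (-1.22), Ahi1 (-1.15), Gria1 (-1.13) and Eif3c (-1.01). Hippocampus minus cortex differed for Igf2 (1.69), Ttr (1.67), Igfbp2 (1.48), Cd74 (1.39), Cyp26b1 (0.92), Nts (-1.70), Pou3f1 (-1.04), Ccn3 (-0.76), Wfs1 (-0.71) and Ywhab (-0.48). Among lists the median differences were 0.213 for neuropeptides and 0.187 for oligodendrocyte markers (amygdala minus hippocampus), -0.170 for GABA signalling, -0.0842 for glutamate receptors, 1.05 for meningeal and 0.313 for striatal markers (amygdala minus cortex), and -0.166 for oligodendrocyte, 0.522 for choroid plexus and 0.911 for meningeal markers (hippocampus minus cortex). In 100 splits of the arrays within regions, 9, 10 and 4 gave as many calls as the real ones, the real one included, with highest other counts of 147, 513 and 307. The highest of these splits keep the labels of 1 region and turn most or all of those of the other, so they measure the sum of the regional effects, which the structure of the samples allows. With 9 and 10 of 100 splits giving as many calls, the first 2 counts were not set apart from chance. For hippocampus against cortex 4 of 100 splits did so, under 5 of 100, but this share was not adjusted for the number of contrasts tested. Since such splits hold real effects, they are a poor measure of chance for all of these contrasts, and no conclusion is drawn from them.

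Most amygdala calls were lower after stress. One stress array that stands apart is argued against, since 431 probe sets were called without it, 77.0% of them lower against 81.0% with it, though only 316 were among the 447 (without both arrays that agreed least with their groups 74.5% of 471 were lower). The other probe sets of the genes called lower had a median change of -0.0460, but they were taken because they were not called. With all other probe sets the median was -0.0577 against -0.597 for the called ones (65.1% of 1 sign), amygdala genes called higher show a like gap (0.00557 against 0.454), handled amygdala against cortex does not (-0.226 against -0.429, 87.1% of 1 sign), and 76.5% of the genes called lower had other probe sets, against 45.9% of those called higher and 27.2% of all genes. Of 3 integrity controls hexokinase was higher in stress amygdala (1.23 against 0.83), beta-actin (2.15 against 2.07) and GAPDH (0.448 against 0.450) were close, and hexokinase was also higher after stress in hippocampus (1.17 against 1.02) and cortex (1.28 against 1.11). These values do not separate signal lost from 1 part of each transcript from reduced expression after stress, and both stay open.

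Meningeal transcripts were lower in stress cortex, and Ttr and Sostdc1, 2 of 7 choroid plexus genes, were higher in stress hippocampus (Aqp1 and Foxj1 were not, and the list call was lost with an estimated correlation, adjusted p = 0.0923). Either could come from the edge of the dissected piece. Of 10 usable meningeal genes, 100% lost more than 20% of their excess over the other regions, but this restates the fall seen before and lower expression in unchanged meninges would give the same, so it decides nothing. For choroid plexus the median change over the 3 genes brighter in handled hippocampus than cortex was 0.204, with 1.62 for Ttr alone, and the test cannot tell. A response of these tissues to stress was not tested.

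The added Bacillus control transcripts of dap were brighter on the handled than on the stress amygdala arrays by 0.569 log2. The controls added at hybridization differed by 0.183, a ratio of 0.322. The interval stated for the test, a 95% bootstrap over the control probe sets, was 0.234 to 0.449 and so below 0.5, but it leaves out the spread between arrays, and over arrays their difference less 0.5 of that of dap had a 95% interval of -0.254 to 0.0508, which spans 0. A difference in hybridization or scanning, or in an earlier step of preparation, may be involved, and neither can be told apart from treatment here.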

How the results depend on the processing

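No named gene or list call turned direction, but with quantile normalization 2 called probe sets did in the averaged effect, 2 in handled amygdala against cortex and 3 in handled hippocampus against cortex, and median centring turned the majority direction of both handled amygdala contrasts. Many counts moved, and the cause was not tested. The fit used 1 shared spread per probe set over all 18 arrays. Median SDs within groups (stress, then handled) were 0.103 and 0.110 log2 in cortex, 0.162 and 0.1285 in amygdala and 0.136 and 0.15 in hippocampus. With only the groups compared, cortex and not amygdala had the most calls, so the order of the regions by count depends on this setting. In amygdala 447 became 186 with only the groups compared, and 197 to 535 when 1 array was left out. In hippocampus 67 became 32 with no trend, 20 with only the groups compared, and 27 to 70 with 1 array out. In cortex 75 became 48 with no filter, 43 with no trend, 621 with array weights, 196 without both outlying arrays, 560 with only the groups compared, and 34 to 44 with 1 array out. The averaged count of 868 became 570 with no trend. For amygdala minus hippocampus 9 became 15 with median centring, 3 with no filter, 16 at the 60th percentile, 3 with no trend, 3 with array weights, 14 without both outlying arrays, 4 with only the groups compared, and 3 to 18 with 1 array out. For amygdala minus cortex 24 became 15 with no filter, 9 with no trend, 60 with array weights, and 11 to 45 with 1 array out. For hippocampus minus cortex 16 became 10 to 16 with 1 array out. The 12 gene list shifts became 3 with an estimated correlation and 9 to 14 with 1 array out. The sharing of amygdala and hippocampus was 0.271 with offset 64, 0.327 at the 60th percentile and 0.126 to 0.257 with 1 array out. That of amygdala and cortex was 0.167, 0.209, 0.197 without both outlying arrays, and 0.0347 to 0.197. That of hippocampus and cortex was 0.274, 0.329, 0.180 and 0.180 to 0.2203.

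With the number in the label as a block the counts were 421, 61, 54, 852, 9, 19, 15, 2705, 4769 and 5240, in the order of the 3 regions, their average, the 3 differences (amygdala minus hippocampus first) and the 3 handled contrasts (against cortex first). Residuals of arrays with equal numbers correlated at -0.0324 to 0.00501 for stress and handled arrays of a region and at -0.0444 to 0.1003 for 1 treatment in 2 regions, against -0.0446 to 0.0467 and -0.147 to 0.1096 for unequal numbers, which gives no sign of pairing by number. The labels do not say what the numbers mark, so shared animals between regions are not excluded.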

Other observations

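Transcripts of monoamine and acetylcholine signalling lay above 0 for 18 of 21 genes in stress amygdala (median 0.14), though none passed and camera did not call the list (adjusted p = 0.0902), whereas fry did (adjusted p = 0.00143). Lpar1, a receptor for lysophosphatidic acid found in oligodendrocytes, fell in all 3 regions (-0.34, -0.52 and -0.40 in amygdala, hippocampus and cortex), while the oligodendrocyte list was called by camera and by fry in hippocampus alone. Genes of hypoxia and glycolysis lay above 0 for 16 of 19 members in stress hippocampus without a call of the list by camera (adjusted p = 0.0606) or fry (adjusted p = 0.1996).

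With 3 arrays in each group there are 10 splits, too few for a share under 0.05. In each regional stress contrast 1 split, the real one, gave as many calls: 447 against at most 0 in amygdala, 67 against 3 in hippocampus and 75 against 0 in cortex. The same held between handled regions, with 2738 against 1 (amygdala and cortex), 4815 against 1 (hippocampus and cortex) and 5289 against 0 (amygdala and hippocampus). For the average, 1 of 100 splits gave as many calls, 868 against at most 125. A split that mixes stress and handled arrays, or regions, puts the real difference into the spread within its groups. That lowers its calls, so none of these counts is a fair measure of chance, and no conclusion is drawn from them.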
